A study of Mus musculus with 15 samples.

How the data were processed

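PolyA RNA of TTF cells from female C57BL6/CAST hybrid mice was sequenced by a commercial provider, per the labels' protocols. The submitters' processing notes list FastQC 0.11.3, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 0.1.19, StringTie 1.3.3 and DESeq2 1.32.0, with the builds mm10 and GRCm38 but no roles. The aligner settings, counter settings, strand setting and annotation are not given in the sources used here. The authors deposited estimated counts per gene and per transcript for all reads, and estimated counts per gene for reads split into genome 1, genome 2 and unassigned. They are named estimated counts because StringTie, the only quantifier listed, derives counts from coverage; the values are whole numbers and were used without further rounding. Which strain is genome 1 is not given in the sources used here. The transcript table of split reads was not used here.

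Columns were matched to samples by name. The knockout columns carry the numbers 2, 9 and 22, which match the titles of 3 knockout lines, and the wild-type columns the numbers 1, 2 and 3. An earlier group of knockout libraries has no line numbers, so these columns may be those libraries of the same lines; the genotype is the same either way. The libraries with SIRT7 added back and those named SIRT7-HY were not analysed here, and neither were the comparisons planned with them. The gene table holds 55487 genes, of which 55227 matched the GENCODE M21 annotation of GRCm38 and 260 did not; the latter held 0.0319% of counts. Chromosomes, coordinates and gene types came from that annotation.

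Total counts lay between 61065582 and 61506413 per library, with 37.0% to 37.9% of the split counts allele-assigned. X-linked allele-assigned counts lay between 486810 and 666856. Pearson's r of log2 CPM was 0.9925 to 0.9931 for wild-type pairs, 0.9531 to 0.9692 for knockout pairs and 0.9479 to 0.9615 between groups. The ranges of knockout pairs and of pairs between groups overlapped, so some knockout lines were no closer to each other than to wild type. No pair of libraries agreed within sampling noise.

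Knockout and wild type were compared with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test on the counts, with TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment; adjusted p under 0.05 was called. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to 1e6 total gene counts per library. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members. The same test compared X-linked with other genes. Allelic ratios were tested with an edgeR quasi-likelihood model with a term per library, an allele term and an allele by group term, for genes with a mean of at least 20 allele-assigned counts per library. Adjusted p-values in the text come from these models. Shares per library were compared by two-sided exact permutation tests in scipy 1.17.1. With 3 libraries against 3 these exact tests cannot go below p = 0.10. Intervals are 95% Wilson intervals. A fold against a group at 0 used a floor of 3 counts over the group.

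The groups, tests, 27 gene lists and rule for named genes were fixed before the data were examined. The plan took the earlier knockout libraries for knockout against wild type and kept later ones out of that fit. The knockout columns used match later titles by name, and this match was made after the files were seen. The rule took Sirt7; the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5 and no overlap of groups, without predicted or unnamed genes; up to 4 members per list by p; Xist, Tsix, Jpx, Ftx and Firre; the 5 X-linked and 5 autosomal genes with the smallest allelic p; and tested escape genes. Other members of a list are covered by its counts, and some genes that the rule selects are not reported here.

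The methods were tested on simulated data drawn from the libraries' means and depths with 200 genes changed. The edgeR test on 16359 genes called 33.7% of genes changed 2-fold and 69.2% of those changed 4-fold for knockout against wild type, and 8 of 16167 unchanged genes. For the allelic test on 12984 genes, noise was first simulated from deviations around the share over all 6 libraries, which counts group differences as noise; it then called 0% of 2-fold and 20% of 4-fold changes. After this low recovery was seen, noise was also simulated from deviations within groups, and the test called 11% and 80%, with 7 of 12784 unchanged genes. Both are given because the noise level was reconsidered after the outcome was known, and small allelic changes can be missed under either. All of these simulations gave wild type and knockout the same spread. In the data the biological coefficient of variation was 0.135 in wild type and 0.378 in knockout, so recovery and false calls may differ there.

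Alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a 2-fold minimum, other coverage minimums of 10 and 50, limma on the logit share with 0.5 added to each count, an estimated correlation, fry, and each library left out in turn. Chromosome medians taken out, limma-voom with group weights, X-linked pseudogenes left out, and Bgn left out were added after seeing the data.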

Results

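The series measured polyA RNA by RNA-seq in TTF cells, the usual abbreviation for tail-tip fibroblasts, from female mice that were hybrids of the C57BL6 and CAST strains. Its title names the sirtuin SIRT7, a nuclear deacylase, and dosage compensation of the X chromosome. Hybrid cells carry many base differences between their chromosome copies, so part of the reads can be assigned to genome 1 or genome 2. The 6 libraries analysed were 3 wild-type libraries, called WT 1, 2 and 3, and 3 SIRT7 knockout libraries, called KO 2, 9 and 22 after the line numbers. The other 9 libraries in the labels were not analysed here. Total gene counts were 61065582, 61412495 and 61506413 in WT 1, 2 and 3, and 61068884, 61476367 and 61194973 in KO 2, 9 and 22. Between 37.0% and 37.9% of the split counts were assigned to a genome.

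Wild-type libraries were closer to each other than knockout libraries were. The biological coefficient of variation was 0.135 within the wild-type group and 0.378 within the knockout group. Mitochondrial genes took 1.47% ± 0.093 of counts in wild type and 1.17% ± 0.0863 in knockout, and the 20 most abundant genes 8.15% ± 0.0726 and 9.92% ± 0.648 (SD, n = 3 each). The labels call the wild-type libraries replicates and do not say whether they came from separate animals or cultures, so p-values measure only the spread between these libraries. Their share of allele-assigned counts from genome 1 was 36.11% on chromosome 6 and 69.49% on chromosome 19. It differed between them by at most 1.802 percentage points on any autosome, while knockout lines lay up to 31.98 points apart. The wild-type libraries thus look like repeats of a single line. Differences between lines and by genotype cannot then be told apart in any comparison here. The knockout lines shared some values unlike wild type, such as 31.62%, 31.85% and 31.72% on chromosome 7 in KO 2, 9 and 22, against 57.63% in wild type. On other chromosomes, such as 11, they differed. Whether these lines arose independently was not established here, while the tests treat them as independent replicates. The labels also do not settle whether the knockout columns were sequenced together with the wild-type ones. If they belong to a later set, set and genotype cannot be told apart.

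Sirt7 (ENSMUSG00000025138, chromosome 11, 120618372 to 120625240 in GRCm38) had gene counts of 833, 1107 and 598 in WT 1, 2 and 3. KO 2, 9 and 22 had 512, 694 and 787 counts. The gene-level change was not past the test (log2 fold change -0.31, SE 0.27, adjusted p = 0.515). The full-length coding transcript Sirt7-201 had 53, 58 and 159 counts in WT 1, 2 and 3, and 2, 0 and 0 counts in KO 2, 9 and 22. Transcripts with retained introns made up most of the remaining counts, and the shorter coding transcript Sirt7-207 had 60, 129 and 0 counts in KO 2, 9 and 22. Counts per transcript are estimates that divide reads among overlapping transcripts.

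The comparison of knockout with wild type asked which genes differed without SIRT7. Rab3b, a small GTPase of vesicle transport, fell from 60.3 ± 8.32 to 0.234 ± 0.047 CPM (SD, n = 3 each; log2 fold change -7.97, SE 0.21, adjusted p = 9.54e-05). Ptges, a prostaglandin E synthase, fell from 48.3 ± 4.84 to 0.480 ± 0.311 CPM, and Slco2a1, a prostaglandin transporter, from 59.2 ± 3.44 to 0.914 ± 0.334 CPM. Pdgfd, a platelet-derived growth factor, rose from 4.03 ± 0.857 to 27.1 ± 1.71 CPM (log2 fold change 2.78, SE 0.19, adjusted p = 0.00220). The smooth muscle actin Actg2 rose from 340 ± 10.96 to 1290 ± 35.0 CPM (log2 fold change 1.96, SE 0.08, adjusted p = 7.50e-04). The calls of these 5 genes held without any 1 of the 6 libraries.

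In all, 1123 of 16678 tested genes changed, with 591 higher and 532 lower in knockout. Of these, 290 rose and 223 fell by at least 2-fold. Groups did not overlap in 5995 tested genes, or 36.0%. Chance gives 10% only where both groups spread alike. Here the coefficient of variation was 0.135 in wild type and 0.378 in knockout, so unchanged genes can separate more often than 10%. The other large rises that the naming rule selected were mt-Td, a mitochondrial tRNA gene (log2 fold change 8.04), Stbd1 (3.92), Cyp4v3 (3.43), Plb1 (3.29), Shroom2 (3.23), Armcx4 (3.11), Chmp4c (3.09), Aoc3 (3.07) and Aspn (2.88). mt-Td had 1, 3 and 4 counts in WT 1, 2 and 3 and 591, 878 and 688 in KO 2, 9 and 22, although mitochondrial genes together took a smaller share in knockout. If the knockout columns belong to a later set, its rise cannot be told apart from a difference between sets. Shroom2 and Armcx4 lie on the X chromosome. The other large falls were Tgfbi (-7.98), Tmem26 (-7.36), Adam33 (-7.22), Pcp4l1 (-5.97), Emilin2 (-5.17), Vldlr (-4.50) and Slc38a4 (-4.45). The imprinted gene Dlk1 had 276, 328 and 534 counts in WT 1, 2 and 3 and 0 counts in every knockout library, at least 379-fold lower against a floor of 3 counts over the group. The count of calls depended on the wild-type libraries: it was 51, 45 and 50 without WT 1, 2 and 3. It was 2482 without KO 22, 2560 with DESeq2 and 396 with no filter on low counts.

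Of 59 tested genes for RNA polymerase I and ribosome biogenesis, 10 fell, 0 rose and 49 did not pass the test; 26 fell when adjusted over the list alone (camera adjusted p = 1.17e-09, adjusted p = 0.816 with an estimated correlation). Noc3l fell by 0.83 (SE 0.12), Gar1 by 0.81 (SE 0.13), Gnl3 by 0.75 (SE 0.11) and Polr1a, the largest subunit of RNA polymerase I, by 0.70 (SE 0.13) on the log2 scale. Of 40 interferon response genes, 8 rose and 32 did not pass, and 23 rose when adjusted over the list alone (camera adjusted p = 2.33e-08, adjusted p = 0.816 with an estimated correlation). Ifit1 rose by 2.06 (SE 0.34), Ifit3b by 1.67 (SE 0.26), Ifit3 by 1.38 (SE 0.19) and Ifi27 by 1.03 (SE 0.17). Reads of Ifit3 and Ifit3b, which are close copies, may be shared between them.

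Of 25 cholesterol synthesis genes, 6 rose and 19 did not pass, and 10 rose when adjusted over the list alone (camera adjusted p = 3.26e-05, adjusted p = 0.378 with an estimated correlation). They included Hmgcs1 (log2 fold change 0.78, SE 0.16) and the X-linked Nsdhl (0.70, SE 0.12). Of 20 genes of the unfolded protein response, which serve protein folding in the endoplasmic reticulum, 4 rose and 16 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.816 with an estimated correlation). The 4 were Pdia6 (0.69), Hsp90b1 (0.58), Selenos (0.45) and Manf (0.36).

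Of 30 integrated stress response genes, 5 fell and 25 did not pass; 9 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.0372, adjusted p = 0.816 with an estimated correlation). The transcription factor Atf4 fell by 0.72 (SE 0.13), and the serine synthesis enzymes Psat1 and Phgdh by 0.73 (SE 0.08) and 0.61 (SE 0.10). Of 75 mitochondrial ribosomal proteins, 4 fell, namely Mrpl12 (-0.83), Mrpl49 (-0.54), Mrpl42 (-0.48) and Mrpl13 (-0.43), and 71 did not pass; 11 fell and 1 rose when adjusted over the list alone (camera adjusted p = 8.60e-04, adjusted p = 0.816 with an estimated correlation). Of 65 cell cycle genes, Uhrf1 (-0.68) and Tyms (-0.55) fell and 63 did not pass, and 0 passed when adjusted over the list alone (camera adjusted p = 0.00516, adjusted p = 0.816 with an estimated correlation).

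These 7 of 23 tested lists were past camera's test with its preset correlation of 0.01. None of the 7 calls held when the correlation was estimated. The integrated stress list was lost without KO 2 (adjusted p = 0.117) and without KO 22 (0.0758), the mitochondrial ribosome list without KO 22 (0.0758), and the cell cycle list without KO 9 (0.0527). Some named list members lie on chromosomes whose median moved the same way, and others do not. The list tests were not run with chromosome medians taken out, so chromosome-wide changes may contribute to them. With those medians taken out, 19 of all named genes lost their call, 2 gained it, 4 changed sign and 101 stayed the same.

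**Figure D1:**
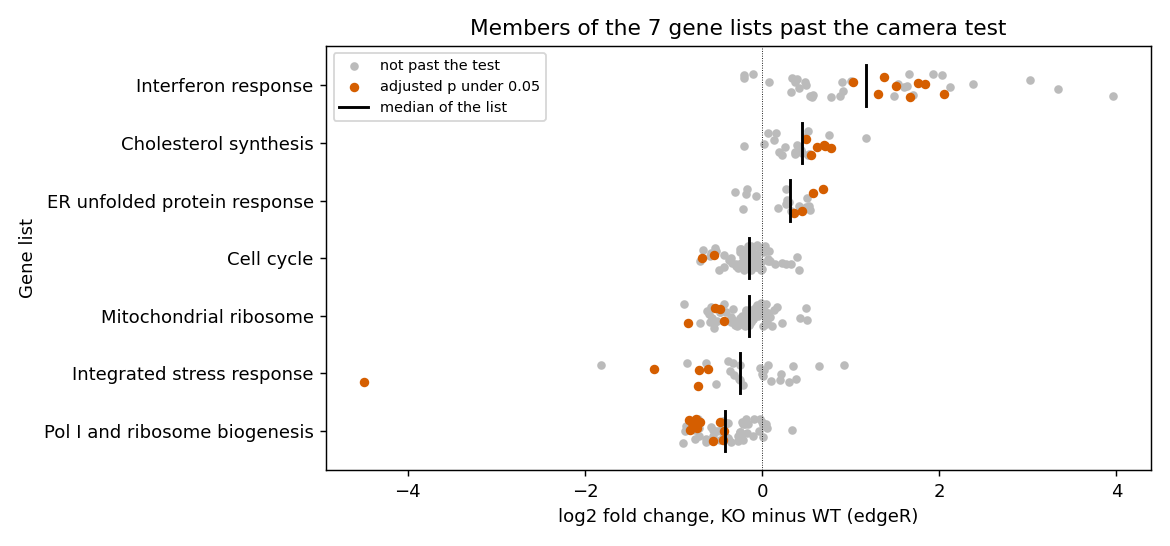
Log2 fold change of knockout minus wild type (x axis, from edgeR) for each member of the 7 gene lists past camera's test (y axis). Each point is a gene, coloured where its adjusted p was under 0.05, and black bars are list medians, which range from -0.42 for ribosome biogenesis to 1.17 for interferon response.

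Col1a2 (log2 fold change 1.25, SE 0.15), Col1a1 (0.93, SE 0.13) and the X-linked Bgn (1.12, SE 0.20) rose, and Timp3 (-0.82, SE 0.07) and Thbs2 (-1.45, SE 0.22) fell. Of 46 fibroblast matrix genes, 6 rose, 2 fell and 38 did not pass; 12 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.167; 0.0272 without KO 2 and 0.0336 without KO 9). Of 27 contractile genes and SRF or YAP targets, 3 rose and 2 fell, with 8 and 2 when adjusted over the list alone. Actg2 and Myh11 (2.39) rose, and Tgfbi and Cnn1 (-3.30) fell; the list's median was 0.29 and its mean -0.02 (camera adjusted p = 0.0711). This p was 0.0247 without KO 9, 0.0486 without WT 1 and 0.377 without KO 22.

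The X chromosome was compared with the autosomes to ask whether its total output differed. Of 577 tested X-linked genes, 44 rose and 14 fell, and 1057 of 16048 autosomal genes changed. The median log2 fold change was 0.11 for X-linked and 0.01 for autosomal genes, a difference of 0.10 (camera in limma, unadjusted p = 0.0138). This call was lost with an estimated correlation (p = 0.313), without KO 9 (0.07, p = 0.134) and with no filter on low counts (0.09, p = 0.133). Several autosomes had larger differences: median changes minus those of all other chromosomes were -0.32 for chromosome 17, -0.26 for chromosome 15, -0.24 for chromosome 19 and 0.20 for chromosome 8. Their camera calls were also lost (adjusted p = 0.447, 0.291, 0.143 and 0.143 with an estimated correlation). X-linked genes took 3.10% ± 0.0139 of all gene counts in wild type and 3.53% ± 0.265 in knockout (SD, n = 3 each; two-sided exact permutation p = 0.10, the smallest that 3 against 3 libraries allow). Without KO 9, whose share was 3.83%, the difference of 0.433 percentage points became 0.280.

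Xist, the RNA that coats the inactive X, had 343 ± 14.3 CPM in wild type and 386 ± 52.6 CPM in knockout (SD, n = 3 each) and did not pass the test (log2 fold change 0.20, SE 0.13, adjusted p = 0.359). Jpx (-0.10) and Ftx (0.01), RNA genes beside Xist, did not pass either, and Tsix was too low to be tested. Firre, an X-linked noncoding RNA, rose (1.36, SE 0.29, adjusted p = 0.0465), a call lost without any of WT 1, 2 and 3, KO 9 or KO 22, with limma-voom, with no filter on low counts and with chromosome medians taken out. It was the only one of 26 tested X inactivation regulators to pass, and 0 passed when adjusted over the list alone (camera adjusted p = 0.993). Among 16 X escape genes, Bgn rose and Kdm5c, a histone demethylase, fell (-0.41, SE 0.09, adjusted p = 0.0468), and 14 did not pass (camera adjusted p = 0.720). The same counts, 1 higher and 1 lower, held when adjusted over the list alone. The Kdm5c call was lost without any of WT 1, 2 and 3, KO 2 or KO 9, with limma-voom, with or without group weights, and with no filter on low counts (adjusted p = 0.0509 to 0.213).

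Allele counts showed which X carried the reads. Genome 1 gave 99.9% ± 0.05 of Xist counts in wild type and 99.8% ± 0.03 in knockout (SD, n = 3 each), and 2.66% ± 0.104 and 2.14% ± 0.160 of the counts of all other X-linked genes. The shares were 2.78%, 2.61% and 2.59% in WT 1, 2 and 3, and 2.16%, 2.28% and 1.97% in KO 2, 9 and 22 (two-sided exact permutation p = 0.10, the smallest possible). The 95% Wilson intervals were 2.73% to 2.82% for WT 1 and 1.93% to 2.002% for KO 22, and such intervals cover counting error only. Bgn had 129 counts from genome 2 in WT 1 and 36553 and 35188 in WT 2 and 3. Its counts from all reads were 75441, 78235 and 82631 in WT 1, 2 and 3, so the low split count did not reflect its expression. Bgn was not alone: Tfe3, named after its values were seen, had 2165, 285 and 202 genome 2 counts in WT 1, 2 and 3. With Bgn left out, chosen after its counts were seen, the X-linked shares were 2.78% ± 0.0138 in wild type and 2.42% ± 0.140 in knockout (exact permutation p = 0.10). With escape genes left out they were 1.76% and 1.67% (exact permutation p = 0.40). With pseudogenes left out, chosen after seeing the data, they were 1.3% in wild type and 1.06% in knockout (exact permutation p = 0.10). Pseudogenes held 7234 of 13216 X-linked genome 1 counts in WT 1, 7277 of 14948 in KO 9 and 6272 of 11374 in KO 22. Their reads may be shared with parent genes, so the shares of all X-linked genes may overstate the output of genome 1. The autosomal share was 52.0% in wild type and 49.6% ± 2.12 (SD) in knockout (exact permutation p = 0.10).

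Part of the 16 tested escape genes had many reads from both genomes. The genome 1 share was 51.9% ± 2.18 in wild type and 45.2% ± 1.78 in knockout for Kdm6a, 42.8% ± 4.60 and 34.5% ± 4.63 for Kdm5c, 42.0% ± 1.88 and 38.5% ± 1.65 for Eif2s3x, 50.3% ± 3.51 and 46.9% ± 4.79 for Pbdc1, and 29.9% ± 1.19 and 29.4% ± 2.95 for Ddx3x (SD, n = 3 each). The noncoding 5530601H04Rik had 37.2% ± 5.33 and 34.7% ± 4.28, and Car5b 13.2% in KO 9 and at most 2.14% in the other libraries. Utp14a had 0 genome 1 counts in all 6 libraries against 877 to 1246 from genome 2, and the mean share in both groups was at most 0.17% for Ogt, Syap1 and Shroom4. None of these 11 passed the allelic test (adjusted p from 0.172 for Kdm5c to 1 for Utp14a, edgeR). Of the others on the escape list, Jpx and Mid1 passed and are given below, while Bgn, Ftx and 1810030O07Rik did not pass. Of 345 X-linked genes with enough allele counts that were neither Xist nor pseudogenes, 15 had at least 10% of counts from genome 1 in wild type and 14 in knockout, and 14 reached it in both groups. Gm27927, an RNA inside the Xist gene, is among them, and was named after its values were seen.

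**Figure D2:**
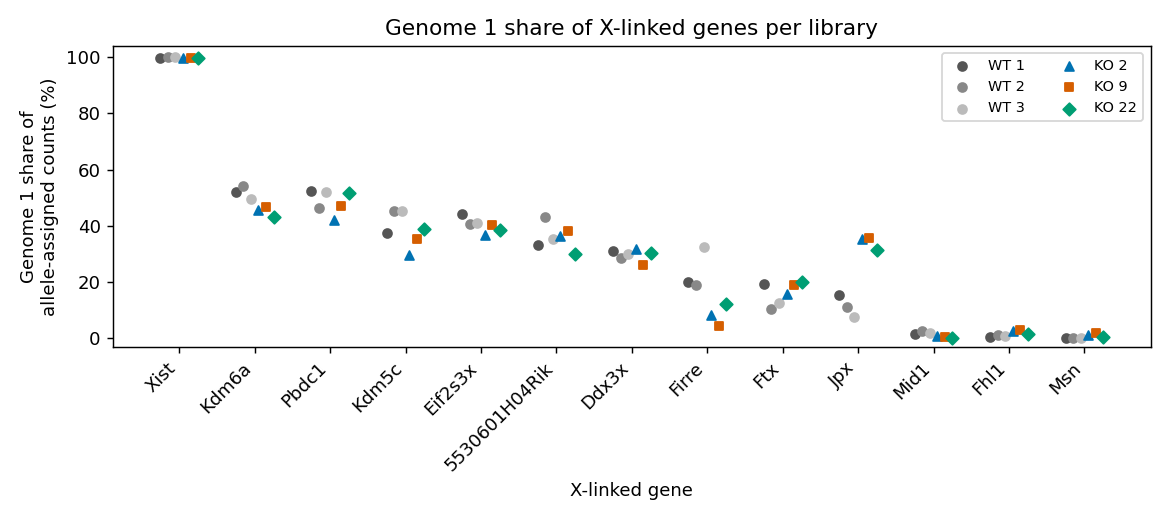
Genome 1 share of allele-assigned counts in percent (y axis) for 13 X-linked genes (x axis), 1 point per library. Xist lies near 100% in every library, and Jpx lies between 7.61% and 15.3% in wild type and between 31.3% and 35.7% in knockout.

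The allelic ratio changed in 6 of 414 tested X-linked genes, and in 0 when adjusted over the X-linked genes alone. The 6 calls thus depended on adjustment together with the autosomal genes. An unadjusted p under 0.05 was seen in 17, a smaller share than chance alone gives at that threshold. Limma on the logit share called 16. The genome 1 share rose for Jpx from 11.3% ± 3.85 to 34.1% ± 2.39 (log2 allelic ratio 2.04, SE 0.41, adjusted p = 0.0165), for Msn from 0.22% ± 0.02 to 1.19% ± 0.61 and for Fhl1 from 0.70% ± 0.41 to 2.29% ± 0.63. It fell for Mid1 from 1.88% ± 0.60 to 0.44% ± 0.20 (log2 allelic ratio -2.17, SE 0.43, adjusted p = 0.0149). Jpx had few genome 1 counts, 13, 11 and 7 in WT 1, 2 and 3 and 25, 25 and 21 in KO 2, 9 and 22. The other 2 called genes were the pseudogene Gm14539, whose reads may be shared with its parent gene, and Prickle3, named after its values were seen. Prickle3 had 3 genome 1 counts in KO 22 and 0 in the other libraries. Its genome 2 counts were 144, 212 and 157 in WT 1, 2 and 3, and 2, 0 and 41 in KO 2, 9 and 22. KO 9 thus had no allele counts for it. Without WT 1, 2 and 3 the number of changed X-linked genes was 3, 0 and 1, and without KO 9 it was 12.

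On the autosomes the allelic ratio changed in 2986 of 12538 tested genes, 23.8% against 1.45% on the X. These rates are not comparable, since the median X-linked gene had no genome 1 counts. The autosomal changes lay on particular chromosomes and mostly went 1 way on each. On chromosome 7, 631 genes moved toward genome 2 and 3 toward genome 1; on chromosome 1, 443 moved toward genome 1 and 2 toward genome 2. The summed genome 1 share of chromosome 7 was 57.6% ± 0.810 in wild type and 31.7% ± 0.119 in knockout, and that of chromosome 6 was 36.1% ± 0.121 and 62.1% ± 1.06 (SD, n = 3 each). Other chromosomes differed between knockout lines: on chromosome 11 the share was 57.9% in KO 2, 31.6% in KO 9 and 63.6% in KO 22, against 57.8% ± 0.298 in wild type.

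Of the 5 autosomal genes with the smallest allelic p, Fstl3, Nes and Fuz went nearly to a single genome and Ivns1abp and Gm2115 did not. The genome 1 share of Fstl3, a follistatin family gene on chromosome 10, rose from 42.4% ± 2.75 to 98.8% ± 0.16 (SD, n = 3 each; log2 allelic ratio 6.83, SE 0.20, adjusted p = 4.28e-04). That of Nes, which encodes nestin on chromosome 3, rose from 76.8% ± 0.14 to 99.6% ± 0.20, and that of Fuz on chromosome 7 fell from 55.8% ± 1.12 to 2.89% ± 0.49. Ivns1abp on chromosome 1 went from 21.03% ± 0.95 to 65.7% ± 1.26, and Gm2115 on chromosome 7 from 63.0% ± 1.06 to 25.8% ± 0.75. Without WT 1, 2 and 3 the count of all changed allelic ratios, 2992, was 1720, 1710 and 1741.

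**Figure D3:**
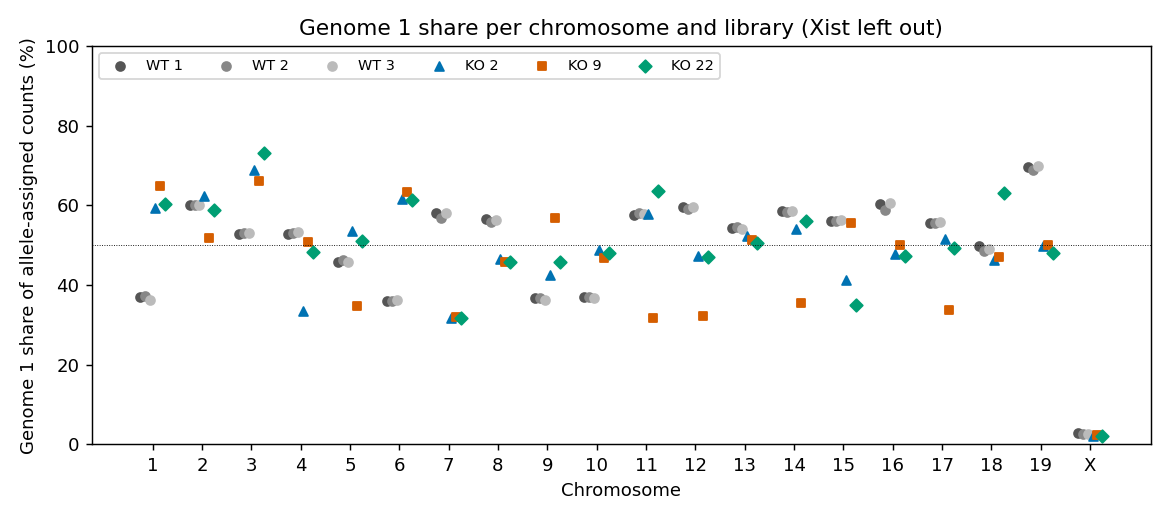
Genome 1 share of allele-assigned counts in percent (y axis) summed over each chromosome (x axis), 1 point per library, with Xist left out. The 3 wild-type libraries lie within 1.80 percentage points of each other on every autosome, while knockout lines lie up to 32.0 points apart on chromosome 11.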

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

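The tests with chromosome medians taken out, group weights, pseudogenes left out and Bgn left out were chosen after seeing the data; the other settings were planned. The count of 1123 changed genes, 591 higher and 532 lower, became 513, 290 and 223 at 2-fold or more, 2560, 1343 and 1217 with DESeq2, and 396, 197 and 199 with no filter on low counts, where many more genes were tested. Leaving out 1 library gave 45 to 2482 changed, 22 to 1305 higher and 23 to 1177 lower; the lowest values came without a wild-type library, whose group varies least, and the cause was not tested further. Limma-voom called 1103, with fewer higher (509) than lower (594), and limma-voom with group weights 1290 (665 and 625).

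The X-linked minus autosomal difference of 0.10 was past the test in other settings but had p = 0.313 with an estimated correlation (0.101), p = 0.133 with no filter (0.086) and p = 0.134 without KO 9; leaving out 1 library gave 0.068 to 0.134. The count of 7 gene lists became 0 with an estimated correlation and 3 with fry, which were cholesterol synthesis, the unfolded protein response and fat cell markers; the last was not among the 7. Changed allelic ratios were 1710 to 3822 with 1 library left out, 1710 to 3810 for autosomal and 0 to 12 for X-linked genes, and 16 X-linked genes with limma on the logit share. The difference in X-linked genome 1 share, -0.519 percentage points, was 0 as a median over genes, because the median gene had no genome 1 counts; it was -0.0873 without escape genes and -0.236 without pseudogenes, and -0.593 to -0.434 with 1 library left out. The X-linked share of counts kept its direction in all 8 alternatives run.

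Values that were not past the test in the main analysis changed sign. With chromosome medians taken out, log2 fold changes were -0.055 for Sirt1, 0.045 for Cdkn1c, 0.003 for Cd68 and -0.083 for Ftx. With limma-voom, with and without group weights, they were -0.067 and -0.068 for Cd14 and -0.054 for Coro1a in both, and Coro1a had -0.003 with no filter. With 1 library left out they ranged from -0.011 to 0.273 for Sirt1, -0.887 to 0.496 for Cdkn1c, -0.411 to 0.444 for Cd14, -0.192 to 0.275 for Coro1a, -0.262 to 0.273 for Cd68, -0.631 to 0.023 for Erbb3 and -0.111 to 0.108 for Ftx. Log2 allelic ratios ranged from -3.539 to 1.396 for Car5b (-1.27 with limma on the logit share), -2.93 to 0.433 for Bgn, -0.121 to 0.079 for Ddx3x and -0.287 to 0.025 for 5530601H04Rik. The direction of camera's test also turned, with adjusted p from 0.877 to 0.973 for X inactivation regulators (0.761 with fry), 0.377 to 0.989 for senescence, 0.617 to 0.973 for Hox, 0.498 to 0.949 for X escape, 0.498 to 0.963 for pigment and glial, 0.109 to 0.655 for p53, 0.642 to 0.910 for cartilage and bone, 0.0272 to 0.880 for fibroblast matrix and 0.403 to 0.886 for glycolysis lists. Over all settings, named genes' fold changes kept direction and side 1166 times, lost the call 264 times, gained it 60 times and changed sign 22 times.

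No paired analysis was possible because the groups compared share fewer than 2 numbers. The fit of all 15 libraries, the comparisons with added-back and HY libraries and the correlations between comparisons were not run. Allele counts on X limit the allelic test, since genes with little expression from genome 1 had few counts.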

Other observations

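The tests of mapping bias, of pseudogene reads, of chromosome medians taken out, of Bgn left out and of shifted against other chromosome pairs were chosen only after the result was seen. Genes of some other lists changed in both directions. The cyclin-dependent kinase inhibitor Cdkn2b (0.47, SE 0.09), the chemokine Ccl5 (2.64, SE 0.47) and Glb1 (0.52, SE 0.10) rose, and Plaur (-1.46, SE 0.22) fell; of 27 senescence genes 3 rose and 2 fell, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.959). Vegfa (-0.70) and Egln3 (-0.76), hypoxia-inducible genes, fell and P4ha1 (0.65) rose; of 33 glycolysis and hypoxia genes 1 rose and 2 fell, 2 and 4 when adjusted over the list alone (0.819). Sirt6 rose (0.54, SE 0.12) among 6 other sirtuins, 2 when adjusted over the list alone (0.588), a call lost without WT 1, 2 or 3, with no filter on low counts (adjusted p = 0.0802) and with chromosome medians taken out (0.37, adjusted p = 0.103). Of 71 respiratory chain genes Ndufb9 (-0.42) and Ndufb8 (-0.39) fell, 0 when adjusted over the list alone (0.122; 0.00792 without KO 2 and 0.498 without KO 22). Of 29 p53 targets Dglucy rose (1.76), 0 when adjusted over the list alone (0.568). Of 26 Hox genes Hoxc11 fell (-0.78), with 2 higher and 2 lower when adjusted over the list alone (0.819).

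Markers of other cell types moved without a common direction. Eng (1.42, SE 0.21) rose among 5 endothelial genes, with 1 higher and 2 lower when adjusted over the list alone; the median was 0.61 while camera's direction was down (adjusted p = 0.720). Acta1 (2.11, SE 0.29) rose among 2 tested muscle genes and Mitf (-1.36, SE 0.25) fell among 6 pigment and glial genes, where 2 rose and 1 fell when adjusted over the list alone (0.819). Of 8 cartilage and bone, 5 fat cell, 4 epithelial and 4 immune genes, 0 passed over all genes; 2 fat cell genes fell when adjusted over the list alone. Camera's adjusted p was 0.727 for cartilage and bone and 0.122 for fat cell genes, while fry gave 0.0498 for the latter. Lists with fewer than 5 tested members had no list test, and Acta1 was also the 1 muscle gene that passed when adjusted over its list alone.

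Imprinted genes show the parent of each genome. In all 6 libraries 8 of 9 paternally expressed genes with allele counts had over 90% of them from genome 1; the exception was Mest. Of 4 maternally expressed genes, 3 had under 10% from genome 1 in all 6 libraries; the exception was H19. The lowest allele counts in a library were 7 for H19, 5 for Cdkn1c and 8 for Plagl1. At most 0.0135% of mitochondrial counts came from genome 1. Of 25 imprinted genes Gnas (0.35) and Sgce (0.86) rose and Dlk1 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.588); of 13 paternally expressed ones 1 rose and 1 fell, the same when adjusted over the list alone (0.167; 0.0487 without KO 22), and of 4 maternally expressed ones 0 passed.

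Whole autosomes differed in genome 1 share between the lines. Of 57 pairs of an autosome and a knockout line, 43 were shifted from wild type by over 5 percentage points, and wild type itself ranged from 36.1% on chromosome 6 to 69.5% on chromosome 19. A few abundant genes do not account for this, since the median gene moved at least 50% as far in 97.67% of shifted pairs, nor does mapping bias alone, since 18 chromosomes ranged over more than 5 points between lines processed alike. Gain or loss of chromosome copies stays open. Total expression lay outside random gene sets in 84.21% of all pairs, past the planned bound of 5%. It did so in 35 of 43 shifted pairs, 13 of 14 others and 18 of 57 wild-type pairs. With most pairs outside, this measure cannot show whether totals follow the shifts. In KO 9, chromosome 7, shifted by -25.8 points, had a total change of -0.00418 (log2), and chromosome 17, shifted by -21.85, had -0.4635. DNA copy number was not used here.

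Changes of total expression by chromosome may contribute to the calls of changed genes. After chromosome medians were taken out, 884 genes were called, among them 63.7% of the 1123 calls, between the bounds of 50% and 90%, and 169 new ones. For the 408 lost calls the median absolute log2 fold change went from 0.615 (SD 0.586) to 0.44 (SD 0.614) with median SE of 0.118 and 0.119. The fold became smaller in 381 of the 408. Chromosome-wide changes and a difference by genotype cannot be told apart for the lost calls. The 6 libraries give 10 splits, too few for a share under 0.05. The real split gave 1123 changed genes and the highest other 2; it gave 2992 changed allelic ratios against 1, and an X-linked minus autosomal difference of 0.101 against 0.079, each reached in 1 of the 10 splits. For gene lists past the threshold, 3 of the 10 splits gave 7 or more, with 8 in the highest other split.

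The X-linked share of genome 1 was lower in each knockout library than in each wild-type library, with a gap of 0.302 percentage points. Without pseudogenes a gap of 0.0467 points stayed, but this does not settle whether their reads account for it. Bgn, with 129 genome 2 counts in WT 1 and 84302 in KO 9, was still counted there. Pseudogenes and Bgn were not left out together. A larger dose of the active X may contribute, but is undecided: genome 1 counts were 0.957 times those of wild type, just above the planned bound of 0.95, and genome 2 counts 1.19 times, while without Bgn alone the ratios were 0.949 and 1.09. Whether a few genes carry the difference also stays open: the groups overlapped without escape genes (1.76% and 1.67%, exact permutation p = 0.40), a gap of 0.0153 points stayed without the 5 genes with most genome 1 counts, and the median difference over genes was 0, which met the sign planned for it, but over genes going both ways (143 higher, 122 lower, 147 equal). A difference by genotype on the inactive X stays open, and no test here separates it from these.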
